A study of Caenorhabditis elegans with 2 samples.

How the data were processed

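Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole late embryos of hermaphrodite Caenorhabditis elegans, 5 h after synchronization by egg bleaching. The worms, strain OP418, carried a transgene that expresses the DM-domain transcription factor DMD-4 with a GFP tag, and chromatin sheared by sonication was precipitated with an antibody against GFP. There was 1 group of 2 biological replicates and no other group, so no comparison between conditions was possible. Control libraries entered the peak calling per the labels and the deposited file listing. Control region lists were not used here.

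The authors deposited region lists in narrowPeak form for 2 genome builds, ce11 and ce10. Each replicate had a list of 30000 candidate regions, a further list of 30000 candidates came from both replicates pooled, and a shorter list held the regions kept by the irreproducible discovery rate (IDR) procedure, which weighs how well replicates rank the same regions. The last are called reproducible peaks, a name for the list that does not mean that each region ranked alike in both replicates. The regions were ranked by the deposited signal value, in arbitrary signal units relative to the control as set by the authors' caller, which are comparable within a list and not as levels between lists. The deposited significance of each region was a -log10 q in the pooled and reproducible lists. In the replicate lists the deposited log10 values of the same column were used only to count regions, and in replicate 1 they reached slightly below 0, to -0.00427. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The files give no read counts, so the depth of each library is unknown. The 95% intervals given are exact (Clopper-Pearson) for shares and conditional for odds ratios. They cover counting error over regions only, and regions are not independent biological replicates.

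All positions refer to ce11, which is the assembly WBcel235 of the reference sequence. The last candidate region on each chromosome ended within that chromosome's length. Genes and transcript starts came from Ensembl annotation release 115, and tRNA isotypes from the RefSeq annotation of the same assembly. Coordinates of ce10 were never converted and served only for counts, replicate values and chromosome shares. Regions were reduced to their summits. A promoter window ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start. A summit counted as near a gene of an RNA class when it lay within 500 bp of the gene, and structural RNA genes are tRNA, snoRNA, snRNA and rRNA genes together.

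Replicates were compared by the overlap, of at least 1 bp, of equally long top lists, with 1000 random draws for chance. A further comparison of the replicates over all candidates is not reported here. Location, chromosome, motif and gene list results set the 652 reproducible peaks against the 29134 pooled candidates that did not overlap them, since these could have been kept. The tests were two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the chromosomes, the locations, the RNA classes, all 6-mers or the 23 gene lists. Motifs were searched within 100 bp either side of the summit. The peaks had a mean GC content of 47.1% and the other candidates 39.7%, so 5940 candidates were drawn to match GC content in bins of 2 points (mean 47.0%). The DM-domain core ACATTGT was compared with 20 scrambled versions. A 6-mer, merged with its reverse complement, counted as enriched at an adjusted p under 0.05 and a ratio of shares of at least 1.5, and as depleted at the same p and a ratio of at most 1 / 1.5. For gene lists, a gene counted when a summit lay in its promoter window, against the genes with a pooled candidate in that window.

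The tests, the gene lists, the naming rule and the alternative settings, except those named as added later, were chosen before the data were examined. The RNA gene classes, the count of depleted 6-mers, the distances of summits from RNA genes, the tRNA isotypes, the gene-name families and the search for sequence copies were added afterwards. The naming rule took the 25 strongest reproducible peaks that overlapped the top 652 candidates of both replicates and had a summit in a promoter window, each named by the gene with the nearest start among those whose window held the summit. It also took the dmd-4 and unc-119 loci and up to 4 members of each gene list with the strongest peaks. Strong peaks at snoRNA and tRNA genes that are named beyond this were chosen after their values were seen.

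The procedures were tested on simulated data. For the sequence tests, simulated peaks and background were both drawn at random from the other candidates. Unlike the real peaks, they therefore did not differ from their background in GC content or location. With nothing planted, 0 of 2080 6-mers were called and the core gave an exact p = 0.0716. With the core planted in 10% of the sequences, both core 6-mers were called. A simulated list of 40 genes raised to 25% was called in 16 of 20 draws, and 0 of 400 lists that were not raised were called. Alternatives covered the overlap rule, the list length, the genome build, the promoter window, the background, the motif window, GC matching, gene assignment, each replicate alone and the removal of regions near transgene loci or RNA genes. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, with blastn 2.17.0 for sequence copies and Matplotlib 3.10.9 for plots.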

Results

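Binding of the DM-domain transcription factor DMD-4, tagged with GFP, was mapped by ChIP-seq in whole late embryos of C. elegans in 2 biological replicates. The experiment asks where in the genome the tagged protein is found. The ce11 list of reproducible peaks held 652 regions with a median width of 450 bp, 643 on the nuclear chromosomes and 9 on the mitochondrial chromosome. The ce10 list of the same experiment held 1138 regions, 1.75 times as many. Both lists were the top of the pooled ranking without gaps, down to pooled rank 652 with a signal of 106.4 in ce11 and rank 1138 with a signal of 88.0 in ce10. The sorted signals of the top 1138 regions differed by at most 0.596% between the builds, so the builds differed in how far down the ranking the list went. Of the 30000 pooled ce11 candidates, 506 had a q of at most 0.05, against 436 in replicate 1 and 566 in replicate 2. All 506 were among the 652 reproducible peaks. The rest of the reproducible peaks, at the weak end of the list, had a q above 0.05, with -log10 q down to 0.952. The depth of the libraries is unknown.

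The first question is how far the 2 replicates marked the same regions. The strongest region was the same in both, at III:8043768-8044193 (ce11), 524 bp upstream of K12H4.5, with signals of 709.9 in replicate 1 and 724.0 in replicate 2. The second was also shared, at III:3499832-3500200, 979 bp upstream of M01F1.9, with 524.6 and 577.7. Of the top 652 candidates of replicate 1, 436 (66.9%, 95% interval 63.1 to 70.5) overlapped the top 652 of replicate 2. Random draws of 652 candidates gave a mean of 2.98% and at most 5.37%. The shared part was 78% among the top 100 and 55.3% among the top 2000. Of the reproducible peaks, 441 (67.6%) lay in the top 652 of both replicates and 11 in neither.

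**Figure D1:**
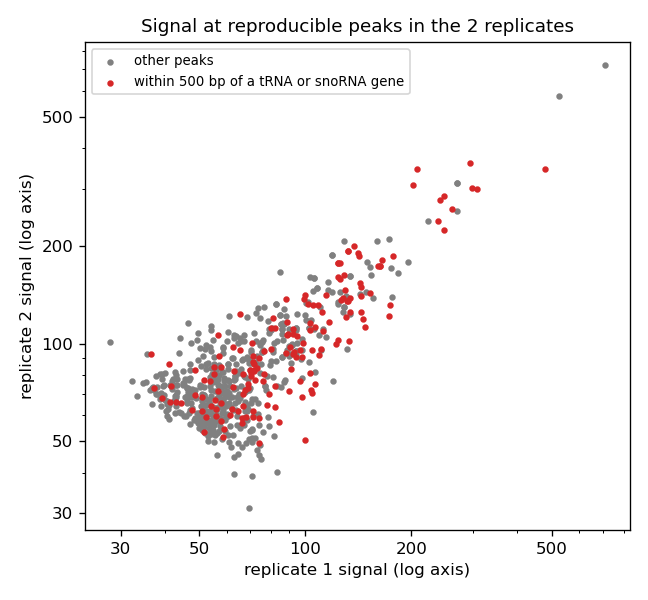
Signal of replicate 1 (x axis, arbitrary units, log axis) and replicate 2 (y axis, arbitrary units, log axis) at the 647 reproducible peaks that were candidates in both, with the 162 peaks within 500 bp of a tRNA or snoRNA gene in red. The peak upstream of K12H4.5 lies at the top right in both replicates, at 709.9 and 724.0.

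The regions with the strongest binding signal included many small RNA genes. Of the 652 reproducible peaks, 17.6% (95% interval 14.8 to 20.8) had a summit within 500 bp of a tRNA gene, against 1.03% of the other candidates. For snoRNA genes, which encode guide RNAs for RNA modification, the share was 7.67% (50 peaks, 5.75 to 9.99) against 0.584%. Examples chosen after their values were seen were the snoRNA gene ZK994.7 (V:8500388-8500712, signal 594.3, rank 6 in replicate 1 and 7 in replicate 2) and W03C9.9 (II:11960667-11960995, 601.0, ranks 5 and 9). The strongest nuclear tRNA peak, chosen in the same way, was at WBGene00000308 (X:13665434-13665724, 521.6, ranks 13 and 11).

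The odds ratio was 20.7 (16.23 to 26.1, adjusted Fisher's exact p = 4.9e-93) for tRNA genes and 14.2 (10.0 to 19.7, adjusted p = 1.4e-35) for snoRNA genes. Each replicate alone gave a similar share, 18.7% and 17.2% of the top 652 candidates for tRNA genes in replicates 1 and 2, and 7.52% in both for snoRNA genes. The share fell with rank: summits near tRNA genes made up 32% of pooled ranks 1 to 100, 23% of ranks 101 to 300, 10.5% of ranks 301 to 652 and 0.520% of ranks 20001 to 30000. By the same exact test, fewer peaks were seen at miRNA genes (10 peaks, odds ratio 3.48, adjusted p = 0.0017), ribosomal protein genes (7, 3.09, adjusted p = 0.012), histone genes (5, 10.2, adjusted p = 5.4e-04) and snRNA genes (4, 3.45, adjusted p = 0.034). At rRNA genes there were 2 peaks, both mitochondrial, against 1 other candidate (odds ratio 89.6, adjusted exact p = 0.0019). Of 612 nuclear tRNA genes, 125 (20.4%) had a peak within 500 bp, and of 346 snoRNA genes 51 (14.7%). Over 21 RefSeq tRNA isotypes, 0 differed from the others at an adjusted or unadjusted p under 0.05 by Fisher's exact test.

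**Figure D2:**
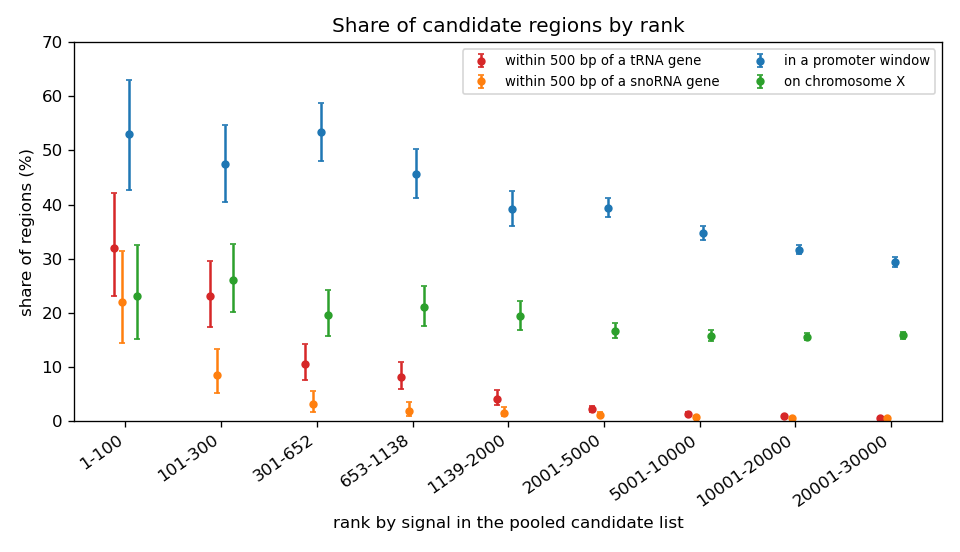
Share of regions (y axis, percent) near tRNA genes, near snoRNA genes, in a promoter window or on chromosome X, by rank in the pooled candidate list (x axis, rank ranges). Bars are exact 95% intervals over regions. The share near tRNA genes was 32% at ranks 1 to 100 and 0.520% at ranks 20001 to 30000.

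Summits lay at different places at the 2 kinds of RNA gene. At 108 nuclear peaks near tRNA genes the median summit was 17 bp into the gene, 61 summits (56.5%) lay inside a tRNA gene and 28 (25.9%, 17.97 to 35.2) upstream of the start. At 50 peaks near snoRNA genes the median was -50 bp, that is upstream, and 42 summits (84.0%, 70.9 to 92.8) were upstream. The upstream share at snoRNA genes exceeded that of the 170 other candidates near snoRNA genes, 50%, with an odds ratio of 5.25 (Fisher's exact p = 1.6e-05). At tRNA genes the peaks and the 298 other candidates were not told apart, 25.9% against 33.6% (odds ratio 0.693, Fisher's exact p = 0.149).

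**Figure D3:**
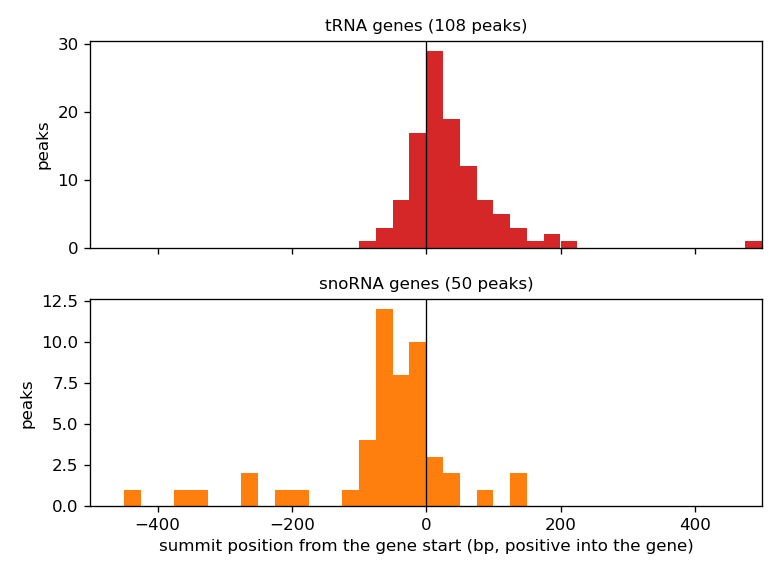
Number of reproducible peaks (y axis) by distance of the summit from the nearest tRNA gene start (top) or snoRNA gene start (bottom) in bp (x axis, positive into the gene). The median was 17 bp at 108 peaks for tRNA and -50 bp at 50 peaks for snoRNA genes.

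The next comparison asks whether binding was at promoters of protein-coding genes. Among the 25 strongest shared promoter peaks were eel-1, the worm HUWE1-type ubiquitin ligase (IV:3050432-3050881, signal 590.7), and ears-2, a glutamyl-tRNA synthetase gene that shares its peak with uncp-18 (IV:390340-390634, 529.3). Others were atx-2, the ataxin-2 gene (III:10461178-10461484, 456.7), tasp-1 (III:10759137-10759376, 372.8), and the peak shared by W03C9.5, the endosomal GTPase gene rab-7 and the germline RNA-binding protein gene mex-1 (II:11967611-11967856, 367.7). A peak with the summit 124 bp downstream of the start of egl-17, a fibroblast growth factor gene, also lay near a tRNA gene (X:489796-490005, 366.1). The remaining nuclear peaks of the 25 were at sre-23, T13C5.6, cfim-2, F59C6.18, chaf-2, idhg-1, Y62F5A.12, npp-6, rps-24, swsn-3, pqn-71 and C28G1.2, with a second region at eel-1. Copies of the summit sequence are given only for the 12 strongest peaks away from structural RNA genes, which do not include all of the 25. Among those 12, similar sequence was found at 57 other loci for the first eel-1 region, 12 for ears-2, 3 for T13C5.6 and 2 for M01F1.9. The ranks of all 25 ran from 1 to 172 in replicate 1 and from 1 to 73 in replicate 2, 4 of the 25 were mitochondrial, and 9 of the 25, 3 mitochondrial ones included, were near a structural RNA gene.

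In total 336 of 652 reproducible peaks (51.5%, 47.6 to 55.4) had the summit in a promoter window, against 32.5% of the other candidates (odds ratio 2.20, adjusted Fisher's exact p = 2.2e-22). Coding exons held 2.45% of the peaks against 16.19% (odds ratio 0.130, adjusted exact p = 7.4e-29) and introns 21.8% against 28.3% (0.706, adjusted p = 4.9e-04). The share between genes did not differ detectably, 19% against 18.2% (adjusted exact p = 0.608). The promoter share stayed level with rank within the list, at 53% of ranks 1 to 100, 47.5% of ranks 101 to 300 and 53.4% of ranks 301 to 652. Promoter summits away from structural RNA genes made up 34%, 38% and 48.6% of all regions in the same rank ranges. Regions near structural RNA genes made up 55%, 32.5% and 13.9% of these ranges. The rise therefore does not show a higher promoter share at weaker peaks among regions away from those genes.

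Chromosome X carried more reproducible peaks than its share of candidates, and much of this went with tRNA genes. Of the 643 nuclear peaks, 144 were on X (22.4%, 19.2 to 25.8), against 16% of the other candidates (odds ratio 1.52, adjusted Fisher's exact p = 1.6e-04). The lowest adjusted exact p of the 5 autosomes was 0.330. X holds 45.1% of the nuclear tRNA genes, and 52 of the 108 nuclear peaks near tRNA genes were on X (48.1%), against 36.6% of the other candidates near tRNA genes (odds ratio 1.61, 1.01 to 2.57, Fisher's exact p = 0.039). Without regions within 500 bp of a tRNA or rRNA gene, X held 17.2% of the peaks against 15.7% (odds ratio 1.11, 0.876 to 1.40, Fisher's exact p = 0.369). A tRNA gene on X had a peak in 63 of 276 cases (22.8%) and one on an autosome in 62 of 336 (18.5%), and no difference was detected by gene (odds ratio 1.31, Fisher's exact p = 0.191).

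The dmd-4 gene itself lay in a group of peaks. Within 50 kb of dmd-4 (X:14857303-14861852, minus strand) there were 7 reproducible peaks among 51 candidates, 4 of them at or above the median signal of the list. The strongest, at X:14861843-14862292 with a signal of 211.5, had its summit 216 bp upstream of a dmd-4 start and ranked 111 in replicate 1 and 126 in replicate 2. A second region, X:14862068-14862517, overlapped it, and regions at X:14858962-14859411 (138.8) and X:14857864-14858313 (118.3) lay in dmd-4 introns. Peaks were also found upstream of epn-1, the epsin gene (X:14818916-14819071, 161.3), and of F31F6.1 (X:14868313-14868762, 144.6). The peak between genes at X:14840949-14841398 (120.9), 4763 bp upstream of egrh-1, ranked 168 in replicate 2 and 5823 in replicate 1. The transgene carries a copy of dmd-4, and reads from the transgene and the chromosomal gene are not separated in the lists. Around unc-119 (III:10902641-10908935), the selection marker of the strain, 1 peak lay within 50 kb, in an intron of another gene (III:10856896-10857168, 324.3). Inside unc-119 itself lay a candidate at III:10903301-10903750 (102.0), which at pooled rank 727 was just outside the reproducible list.

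**Figure D4:**
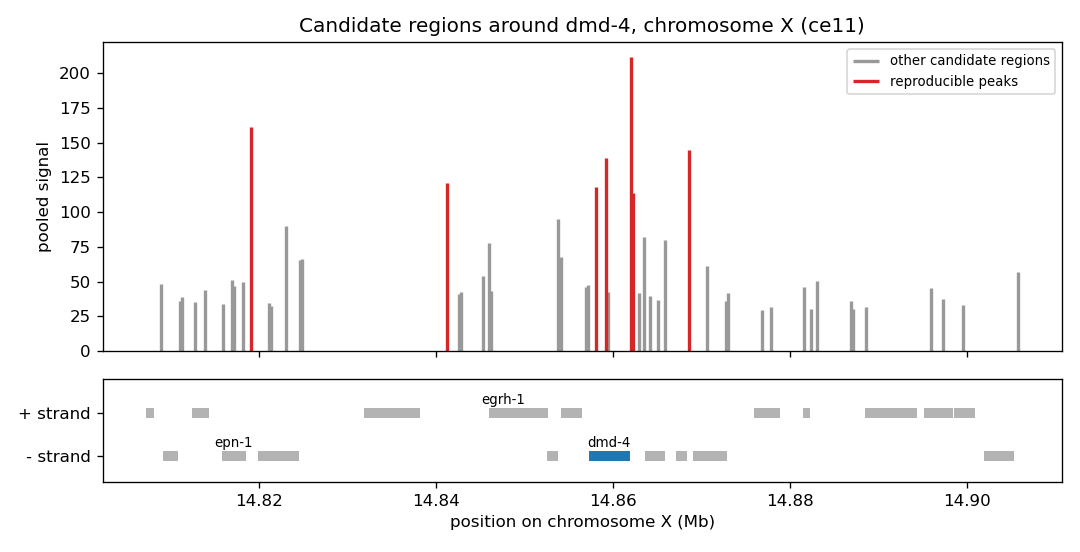
Pooled signal (y axis, arbitrary units) at the summits of candidate regions within 50 kb of dmd-4 on chromosome X of ce11 (x axis, Mb), with reproducible peaks in red, and protein-coding genes by strand below. The highest of the 7 reproducible peaks, with a signal of 211.5, lies just upstream of dmd-4, which is on the minus strand.

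The core ACATTGT is known from sites of the DM-domain proteins DMRT1 and MAB-3. Only exact matches were searched, and a site of DMD-4 itself was not tested. The core ACATTGT was not detectably more frequent at the peaks. It occurred within 100 bp of 19 of 652 summits (2.91%) against 2.69% of GC-matched candidates (odds ratio 1.08, 0.632 to 1.76, Fisher's exact p = 0.704). The longer form ATACATTGT occurred at 0 peaks, against 0.135% of matched candidates (Fisher's exact p = 1). The 20 scrambled cores gave odds ratios from 0.25 to 1.93, 5 of them with an unadjusted p under 0.05, all 5 less frequent at the peaks. Scrambled cores thus also passed this exact test, so its p for a single sequence is only a rough guide.

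Other short sequences differed in frequency between the peaks and candidates matched on GC content. Of 2080 6-mers, 287 were depleted and 194 were enriched, led by CGCACA (21% of peaks against 7.69%, adjusted Fisher's exact p = 4.1e-20), GCGCGC (15.6% against 4.66%, adjusted p = 1.0e-19) and GAGAGA (36% against 19.2%, adjusted p = 1.3e-18). GTTCGA, part of the internal promoter element of tRNA genes known as the B box, was in 18.9% against 7.76% (adjusted exact p = 4.7e-15). At the 481 peaks away from structural RNA genes CGCACA was in 23.7% against 7.75% and GAGAGA in 37.8% against 18.6%, while GTTCGA was in 6.24% against 7.32% (adjusted exact p = 0.64). The 2 6-mers of the DM core, ACATTG and ACAATG, were in 10.3% and 9.51% of all peaks, against 9.93% and 9.76%. Peaks and other candidates also differed in their shares of promoters and coding exons. No background matched on location was run for 6-mers, so the enriched and depleted 6-mers are not separated from differences in location.

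Gene lists for tissues of the embryo showed few members with a peak, but so did all protein-coding genes with a candidate, 414 of 7970. No tissue list was told apart from the other genes at an adjusted p under 0.05 by Fisher's exact test. DMD-4 is known from sensory neurons of the head and tail and from the pharynx. The lists for phasmid sensory neurons (0 of 2 genes with a candidate), pharynx muscle and regulators (0 of 13) and pharynx gland and cuticle (0 of 5) had none at a reproducible peak. These lists held 10, 21 and 18 genes, so many of their members had no candidate and could not have been counted. Pan-neuronal genes had 3 of 23, syd-2 (X:10555445-10555894, signal 142.9), unc-14 (I:7128090-7128539, 122.1) and maco-1 (I:6608018-6608467, 108.9), with an odds ratio of 2.75 and adjusted exact p = 0.877. The cilium list had 1 of 20, daf-19, the ciliary regulator of the RFX family (II:10169221-10169670, 143.0). The axon guidance list had 2 of 33, the adhesion gene sax-7 and unc-115, and the neuropeptide list 1 of 37, flp-23, whose peak was near a tRNA gene. Body wall muscle had 2 of 34, the paramyosin gene unc-15 and unc-112. Epidermis had let-413 as 1 of 24, and the germline list mex-1 as 1 of 21.

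Counts of 0 were also found for neurotransmitter genes (of 7), neuronal identity factors (of 18), glia (of 9), intestine (of 13), sex determination and dosage compensation (of 25), Hox genes and cofactors (of 8) and homeobox genes with ceh names (of 32). Of the DM-domain family, 1 of 8 had a peak, dmd-4 itself. Nuclear hormone receptors had 3 of 91 (nhr-255, nhr-142 and nhr-32), heat shock and proteostasis genes 2 of 25 (hsp-1 and hsp-60), and chemoreceptors 4 of 68 (srh-89, srh-269, srh-34 and sri-5). Over all protein-coding genes, 414 of the 7970 with a candidate in the promoter window had a reproducible peak. The small lists limit what could be detected.

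Histone genes were the 1 list of 23 past the adjusted threshold. Of 25 histone genes with a candidate, 6 had a peak (24.0% against 5.14%, odds ratio 5.83, adjusted Fisher's exact p = 0.033), and these rested on 4 distinct peaks. The pair his-67 and his-68 shared I:9988733-9989182 (signal 202.4), and his-61 and his-62 shared IV:7486206-7486655 (127.0). The others were his-37 (V:9546775-9547224, 110.9) and his-72 (III:12368746-12369195, 110.1), both close to the lowest signal of the list, 106.4. The gene his-72 is a histone H3.3 gene rather than a replication histone, and its peak was near a snoRNA gene. With the top 652 candidates of replicate 2 alone the odds ratio was 4.04 (adjusted exact p = 0.30), and with those of replicate 1 alone 5.43 (adjusted exact p = 0.11). Cytosolic ribosomal proteins had 7 of 63, among them rps-24 (IV:385058-385507, 293.5), rpl-3 (III:3867499-3867636, 227.6), rpl-35 (III:7854458-7854907, 167.1) and rps-12 (III:5678901-5679350, 166.9), with an odds ratio of 2.30 and adjusted exact p = 0.504 (0.044 unadjusted).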

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

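The tests of chance clustering around dmd-4 and of tRNA and snoRNA peaks as such were chosen after the results were seen. A signal appeared on the mitochondrial chromosome, which lies outside the nuclear comparisons: 9 of the 652 reproducible peaks (1.38%, 0.633 to 2.60) were mitochondrial, of 12 mitochondrial candidates, with signals from 129.97 to 810.8. Some of them were candidates in only 1 replicate. M:12463-12622 (signal 545.5) had no overlapping candidate in replicate 2. M:6225-6674 (272.2), M:3739-4188 (271.8) and M:12904-13353 (250.8) had none in replicate 1. Of all 652 reproducible peaks, 647 were candidates in both replicates.

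Peaks near tRNA genes were weighed against 3 technical explanations, and with 1 group no biological explanation was tested. GC content is argued against, since the odds ratio was 14.9 with a GC-matched background (Fisher's exact p = 5.0e-66). Reads shared between gene copies stay open. The 140 nuclear tRNA genes whose exact sequence occurs once gave an odds ratio of 12.4 (7.14 to 20.7, exact p = 1.4e-14). Summits near such a gene counted even where a tRNA gene with copies also lay nearby, and near-identical copies were treated as different. That comparison therefore cannot decide on shared reads. Signal at highly transcribed loci in general stays open as a candidate explanation. The snRNA, rRNA, ribosomal protein and histone genes, tested together, also had more nuclear peaks, 16 against 0.608% of candidates (odds ratio 4.17, 2.32 to 7.02, exact p = 5.1e-06). No nuclear peak was near an rRNA gene, since both rRNA peaks were mitochondrial. Peaks that were also near a tRNA or snoRNA gene, such as the one at rps-12, were not left out. The odds ratio of these classes was less than the 19.5 (15.3 to 24.8) of tRNA genes on the same chromosomes. A precipitation from worms without the tag, not analysed here, would be the direct test.

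For the peaks around dmd-4, chance clustering is argued against. Of 10000 centres drawn at random from the candidate summits of chromosome X, 1.18% had at least 7 peaks within the same distance. Candidates around dmd-4 were not left out of the draw, so this share includes that locus itself. With the count of each alternative list the share ran from 0.57% to 1.02%. Extra copies of the locus in the transgene cannot be told apart from binding, since the 20 weak candidates within 20 kb had a median signal of 44.5, at percentile 81.1 of equally sized neighbouring sets elsewhere on X (median 40.9). That lies between the percentiles set beforehand for and against extra copies. Binding of DMD-4 at its own gene may add to the signal, and the lists do not separate it from the transgene.

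For the higher share of peaks on chromosome X, tRNA genes on X are a candidate explanation: without regions near tRNA or rRNA genes the odds ratio fell from 1.52 (22.4% against 16%) to 1.11 (0.876 to 1.40, 17.2% against 15.7%). The call ended because the difference itself shrank, with 535 of the 643 peaks still tested. The dmd-4 neighbourhood is argued against as the whole cause, since the odds ratio was 1.46 (exact p = 1.9e-04) without regions within 50 kb of it. GC content is argued against as well, with 1.43 (exact p = 5.3e-04) against matched candidates. A part from sites other than tRNA genes is not excluded by the interval.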

How the results depend on the processing

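Alternatives without mitochondrial regions and regions near structural RNA genes, with the longer list, with promoter summits on both sides, and all for tRNA and snoRNA genes and depleted 6-mers and for chance around dmd-4 were chosen after the data were seen. The promoter, tRNA and snoRNA results kept their direction and side of the threshold under each alternative run, with odds ratios from 1.897 to 3.11, 14.9 to 32.4 and 8.73 to 23.2. So did the coding exon result, from 0.0643 for the stricter list to 0.290 for the longer list. The X odds ratio was 1.04 (exact p = 0.76) without regions near dmd-4, unc-119, tRNA or rRNA genes and 1.24 (p = 0.068) without mitochondrial regions and those near structural RNA genes. The DM core, never past the threshold, went below 1 with the longer list (0.937), 200 bp windows (0.943) and the long form (0, no peak), and ran from 0.803 to 1.25 with 1 replicate left out. It was 1.76 (exact p = 0.288) with 50 bp windows and 1.39 (exact p = 0.192) without regions near dmd-4, unc-119, tRNA or rRNA genes. The 6-mer count was 428 without GC matching, and the cause was not tested. Of the 194, 87.1% were kept there, the most of any alternative, with 74.2% for the stricter list, 67.01% for the longer list and 66.5% with 50 bp windows, the fewest. The 287 depleted 6-mers became 149 with 50 bp windows. GTTCGA fell to an odds ratio of 0.842 away from structural RNA genes. The number of enriched gene lists was 0 for the stricter list, for the longer list, away from structural RNA genes, and with either replicate left out (0 in both cases). It was 2 against all protein-coding genes (ribosomal proteins added) and 2 with the nearest start (pan-neuronal genes added). The overlap of top regions was 60.6% with summits within 100 bp, 72.7% for the shorter list and 58.1% for the longer list, and the cause was not tested. It was 59.4% in ce10, where the list held 1138 peaks, and also 59.4% for the top 1138 in ce11. The 7 peaks around dmd-4 became 4 for the stricter list, 6 and 5 without replicates 1 and 2, and 9 for the longer list. Comparisons of replicates allow no replicate to be left out, and unknown depth limits statements on weak regions.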

Other observations

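The tests of summit positions, gene-name families and sequence copies were chosen after the results were seen. Summits of peaks near snoRNA genes were upstream of the gene more often than those near tRNA genes (odds ratio 15, 5.93 to 40.8, Fisher's exact p = 6.8e-12). RNA polymerase III uses promoter elements inside tRNA genes, and many snoRNA genes of C. elegans are also known to be bound by polymerase III. The positions are consistent with a hypothesis that the precipitated chromatin may follow polymerase III promoters, with elements upstream at snoRNA genes. The same data gave the idea and the test, and whether DMD-4 itself or open chromatin leads to the signal was not tested.

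The share of peaks on chromosome X was compared in further ways. Inside promoter windows X held 54 of 329 peaks against 14.5% of the other candidates (odds ratio 1.15, 0.841 to 1.56, exact p = 0.341), and outside them 28.7% against 16.6% (2.01, 1.55 to 2.59, p = 1.7e-07). Whether the X share comes from sites away from promoters cannot be told apart from a smaller rise at all sites, since the interval inside promoters includes both. A single replicate library as the source is argued against, since the lower of the odds ratios of the 2 replicates was 1.49 (exact p = 5.4e-05).

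Gene-name families gave no further group: of 66 families with at least 10 genes in the background, 0 passed the adjusted threshold by Fisher's exact test, and 3 had an unadjusted p under 0.05. Copies of the summit sequence elsewhere in the genome were counted for nuclear peaks, against sampled candidates. Among the peaks at ranks 1 to 100 away from structural RNA genes, 14 of 43 (32.6%) had another copy of at least 100 bp at 80% identity, against 15% of candidates (odds ratio 2.73, 1.32 to 5.41, Fisher's exact p = 0.0042). At 90% identity this odds ratio was 4.14 (exact p = 0.0011), and over 150 bp it was 2.35 (exact p = 0.052). Over all 481 peaks away from structural RNA genes the odds ratios at the same 3 settings were 0.806, 1.46 and 0.807 (exact p = 0.170, 0.050 and 0.317). Over all 643 nuclear peaks they were 1.09, 1.93 and 0.647 (exact p = 0.488, 5.1e-05 and 0.016), so the direction there changed with the setting. Of the 12 strongest peaks away from structural RNA genes, the first eel-1 region, IV:3050432-3050881, had 57 such loci elsewhere, ears-2 had 12, T13C5.6 had 3 and M01F1.9 had 2, and 0 were found for the others.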
